A study of Mus musculus with 9 samples.

How the data were processed

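RNA came from TAMH cells kept for 2, 6 or 24 h in control medium or with APAP or AMAP at 2 mM, in 2 dishes per treatment as the labels state, and was hybridised to 9 Affymetrix mouse arrays of the 430A_2 type, 1 per treatment and time. The design text calls the series preliminary. The deposited values are log2 expression values per probe set, made with RMA in Affymetrix Expression Console per the submitters' processing notes. The software version, and whether all arrays were normalized in a single run, are not given in the sources used here. RMA sets the distributions of probe intensities equal, so a change in total RNA would not show, and it narrows differences of dim probe sets. The probe-set values were not fully alike. Their lower quartile was 3.92 for APAP at 6 h, 3.815 for APAP at 24 h and 3.84 for AMAP at 24 h. On the other arrays it lay between 3.497 and 3.628. Groups were taken from the sample titles.

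The table held 22690 probe sets, of which 64 were control probe sets and stayed out of genes and tests. GEO's platform annotation gave 1 gene symbol for 20380 probe sets, several for 691 and none for 1555. The symbols of 13 probe sets were updated through the RefSeq gene table. A gene was represented by the probe set with 1 symbol and the highest mean over the 9 arrays, which gave 12393 genes, 4956 of them with more than 1 probe set. Expressed genes, 6700, had a mean at or above 5.67, the median of the probe-set means. No group has a replicate array, and precision is limited by the number of arrays.

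At each time the log2 difference of 2 arrays was taken, and genes were counted where it reached 1, which is 2-fold, and the higher array was at or above 5.66, the median of all values. For effects shared by the times, limma 3.58.1 in R 4.3.3 fitted treatment with time as a block over all 9 arrays, with 4 residual degrees of freedom, and Benjamini-Hochberg adjusted p-values under 0.05 were called. A second fit added slopes on log2 time, with 2 residual degrees of freedom. A fit of this kind treats treatment by time as error, so an effect at 1 time only raises the spread. The residual SD had a median of 0.253 log2.

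There were 23 gene lists, 19 of pathways and 4 of cell-type markers, fixed before the data were examined, as were the designs and named-gene rule. The pathways were p53 targets, mitosis, DNA replication, NRF2 targets, ATF4 stress response, ER chaperones, heat shock, immediate-early and MAPK feedback, NF-kB and inflammation, interferon, cholesterol synthesis, fatty acid oxidation, xenobiotic metabolism, hepatocyte identity, glycolysis and hypoxia, respiratory chain, apoptosis regulators, matrix and TGF-beta response, and ribosome biogenesis. The cell types were macrophage, stellate cell and fibroblast, endothelial cell, and cholangiocyte. Some genes are in more than 1 list, so the lists are not independent. Ccn1 and Ccn2 are in the immediate-early and matrix lists, Thbs1 in p53 and matrix, and Atf3 in ATF4 and immediate-early. Sesn2 is in p53 and ATF4, Cxcl10 in NF-kB and interferon, and Ephx1 in p53, NRF2 and xenobiotic metabolism. The 20 lists with at least 3 expressed members were tested with camera at a preset correlation of 0.01, adjusted over 60 tests, with an estimated correlation and with fry beside it. For a single time a list's median was placed among 10000 random lists of the same size, drawn within 20 bins of mean expression, as a description of these arrays.

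Named genes followed a fixed rule. They were the 5 highest and 5 lowest genes past the threshold of the shared fit, of which there were none, and the 5 highest and 5 lowest of those 2-fold apart at each time. Up to 4 members of each described list with the largest difference at any time in that contrast, and Cdkn1a and Mdm2, were added. Trp53, the other gene of the rule, is not analysed here. The genes of a list given in a contrast under another time follow the same rule. Unchanged groups against shared controls were simulated 100 times from each gene's residual SD.

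The fits were tested on simulated arrays of 6700 genes with 200 changed in APAP. The shared fit found 0% of genes changed by 0.5 log2, 48.5% by 1 and 89.5% by 2, and the slope fit 0%, 62.5% and 97% at slopes of 0.5, 1 and 2. Camera found a list of 31 genes shifted by 0.5 and no list when none was shifted, in arrays simulated with independent genes. Of 200 random lists moved by 0.5, 100% lay above the upper percentile bound, and 3% of unmoved ones did. These lists were drawn from shuffled genes without matching on expression. The 3% therefore does not hold for lists whose genes vary together, which can lie beyond all random lists more often.

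The alternatives set in advance were a 1.5-fold threshold, no filter on low values, the mean of all probe sets of a gene, cyclic loess, median centring, trended and robust variance priors, no time block, only the 6 arrays compared, linear time, other set tests and leaving out each time. Chosen after the data were seen were the spike-in ratio as a covariate, leaving out the 3 arrays that stand apart, the check by a further probe set and the slopes of lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.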

Results

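Gene expression was measured in TAMH cells, a mouse hepatocyte line from animals transgenic for TGF-alpha, after exposure to acetaminophen (APAP), to its meta regioisomer (AMAP) or to control medium. In the study's title AMAP is the less hepatotoxic compound, and p53 is named as a contributor to the difference in expression. The compounds carry the same groups and differ in the position of the hydroxyl group on the ring, para in APAP and meta in AMAP. Both were given at 2 mM, and cells were harvested after 2, 6 or 24 h. The 9 arrays give 1 array for each of the 3 treatments at each of the 3 times, so that a difference at a single time has no replicate check and is given as a value without a p. Values are log2 units after RMA. Of 12393 named genes, 6700 had a mean value at or above the median of all probe sets and are called expressed. Trp53 itself is not analysed here. The number of arrays limits the precision.

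The arrays did not all behave alike. APAP at 6 h, APAP at 24 h and AMAP at 24 h had loadings of 0.60, 0.37 and 0.37 on the first principal component, which held 49.2% of the variance, while the other 6 arrays lay between -0.36 and -0.01. On the same 3 arrays the middle probe set of the bacterial dap transcript, a control RNA that does not come from the cells, read lower against its 3′ probe set, with log2 ratios of -1.72, -1.58 and -1.95 against -0.60 to -0.44 on the other 6. A further probe set of the same gene offers a check of a single-array difference. Of the genes 2-fold apart that had such an expressed probe set, it followed in the same direction by at least 0.5 log2 in 96.3%, 97.1% and 93.9% for the 3 comparisons at 2 h. At 6 and 24 h it followed in 28.0% to 51.0%. Between control arrays it followed in 93.3% for 24 against 2 h, but in 65.0% for 6 against 2 h and 56.7% for 24 against 6 h. The check thus bears on the signal of a gene and not on treatment, and the control array of 6 h also had lower shares. The differences at 2 h are therefore given first and at most length.

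**Figure D1:**
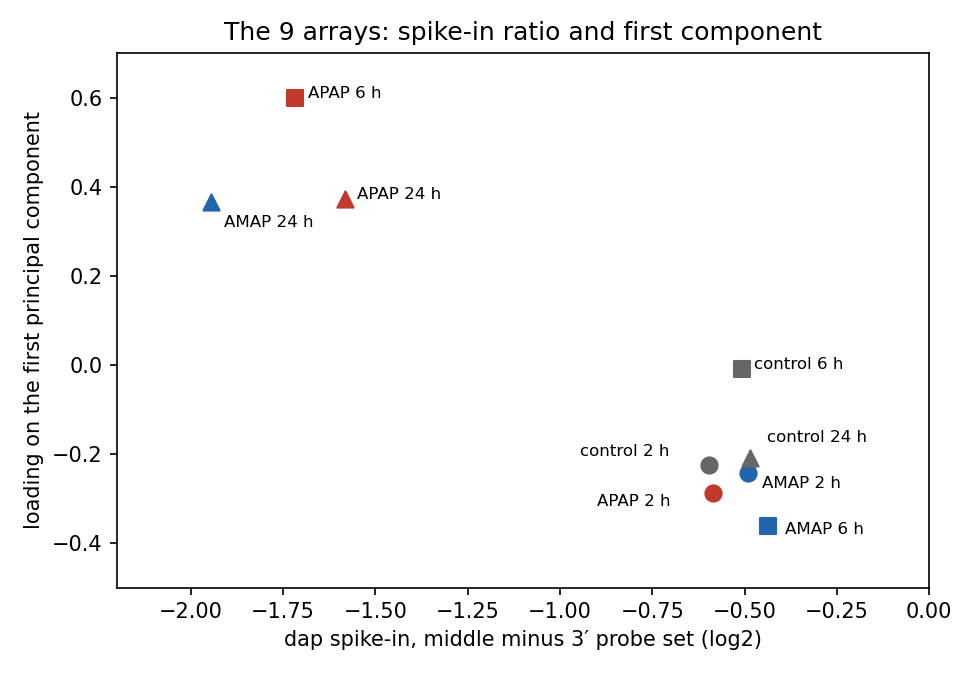
Each point is 1 of the 9 arrays, placed by the log2 ratio of the middle to the 3′ probe set of the dap spike-in (x axis) and its loading on the first principal component (y axis); colour marks control, APAP and AMAP, and shape marks 2, 6 and 24 h. APAP 6 h, APAP 24 h and AMAP 24 h lie at ratios of -1.95 to -1.58, the other 6 at -0.60 to -0.44.

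**Figure D2:**
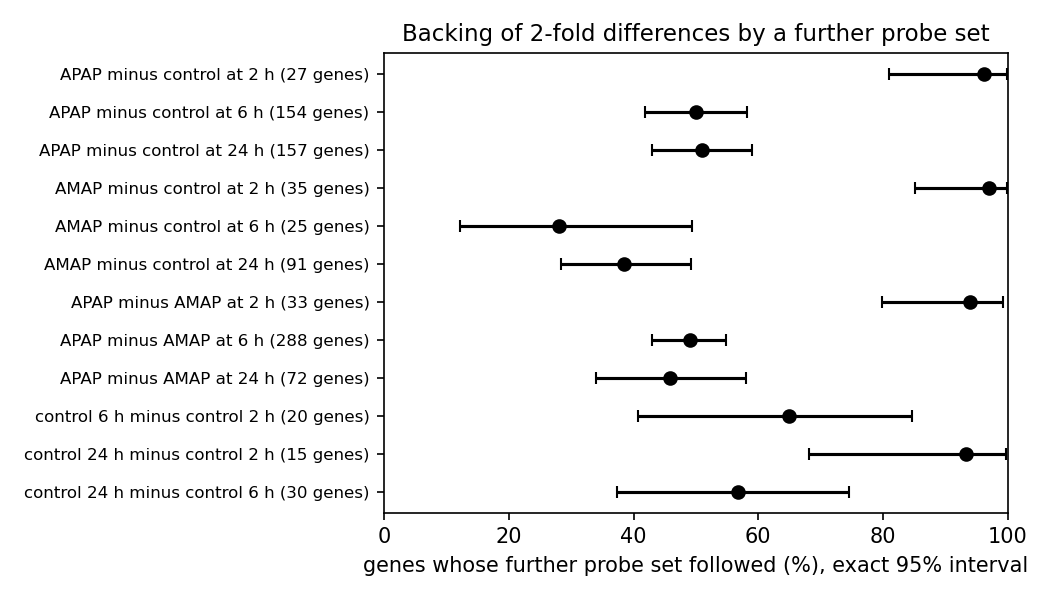
Points give, for each of 9 comparisons of single arrays and 3 comparisons between control arrays, the percent of genes 2-fold apart whose further probe set went the same way by at least 0.5 log2 (x axis), with exact 95% binomial intervals as bars. The comparisons of treatments at 2 h lie between 93.9% and 97.1%, those at 6 and 24 h between 28.0% and 51.0%.

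AMAP against control at 2 h. After 2 h in AMAP, stress and growth-signal transcription factors and p53 targets were higher than in control, while mitotic genes were lower. Atf3, a stress-induced transcription factor, was 15.3-fold higher, from 6.66 to 10.59 on the log2 scale. Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, was higher by 1.68 log2 and Mdm2, the ubiquitin ligase that limits p53, by 1.42. In all, 93 genes were at least 2-fold higher and 30 at least 2-fold lower. For scale, control arrays of different times differed 2-fold in 59 to 82 genes.

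Of 31 expressed p53 targets, 28 were higher in AMAP and 3 lower, with a median difference of 0.69 log2, above all 10000 random lists of like expression. Btg2, an antiproliferative gene, and Plk2, a stress-responsive kinase, were each higher by 1.51, and Pmaip1, which encodes the BH3-only protein Noxa, by 0.99. Of 26 expressed immediate-early and MAPK feedback genes, 25 were higher, with a median of 0.90. Among them were Jun (2.33), Junb (1.92) and Egr1 (1.47). The AP-1 partner Fos read 1.69 higher from a low level. The highest differences also included the cytokines Csf2 (2.96) and Lif (2.25) and the epithelial envelope gene Sprr1a (2.64). Of 24 genes of the ATF4 stress response, 23 were higher, with a median of 0.44. Ddit3, which encodes the stress factor CHOP, was higher by 1.71, Ppp1r15a, which directs dephosphorylation of eIF2α, by 1.49, and Nupr1 by 1.15.

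All 23 expressed mitotic genes were lower in AMAP at 2 h, with a median of -0.74 log2, below all 10000 random lists, and 13 of them were lower by at least 1.5-fold. Ube2c, of the anaphase-promoting complex pathway, differed by -1.35, the spindle motor Kif11 by -1.14 and the spindle protein Nusap1 by -1.09. The 22 expressed DNA replication genes had a median of 0.00, with 10 higher and 10 lower. Of 23 hepatocyte identity genes 19 were lower, with a median of -0.29; the liver transcription factors Foxa1 and Foxa2 differed by -1.32 and -0.99 and the fibrinogen chain Fga by -0.83. The lowest genes were the acute-phase gene Crp (-1.67), the adaptor Grb7 (-1.66), the transcription factors Klf15 (-1.62) and Spib (-1.43), and Cdo1 (-1.57), which oxidises cysteine. Matrix and TGF-beta response genes had a median of 0.72, with Ccn1 at 1.79, Ccn2 at 1.24, Thbs1 at 1.15 and Smad7 at 1.10. Of these, Ccn1 and Ccn2 are also in the immediate-early list and Thbs1 in that of p53 targets. The chemokine Cxcl10 was higher by 1.89, although 5 of the 6 expressed interferon genes were lower. Slc2a1 (0.91) and Hk2 (1.01), which take up and phosphorylate glucose, were higher.

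APAP against control at 2 h. At 2 h in APAP, genes of ribosome biogenesis and matrix response and the cholangiocyte markers were higher than in control and genes of liver metabolism lower. Sprr1a was 6.18-fold higher and Lamb3, a laminin chain of epithelial basement membranes, 4.99-fold. Nucleolar genes were higher throughout, 19 of 19 expressed members, and 12 of 14 genes of fatty acid oxidation were lower. The p53 targets had a median of 0.10, with Cdkn1a at 0.55 and Mdm2 at 0.10. There were 63 genes at least 2-fold higher and 77 at least 2-fold lower, or 69 and 67 under cyclic loess.

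The ribosome biogenesis list had a median of 0.50 log2, above all 10000 random lists, with Mybbp1a at 0.70, Nop58 at 0.63 and Nop2 at 0.42. The AP-1 member Fosl1 (2.25), Csf2 (2.25) and the cardiac troponin gene Tnnt2 (2.19) were among the highest. Of the cholangiocyte markers, the keratins Krt19 and Krt7 were higher by 2.11 and 1.44 and Sox9 by 0.06. Of 11 matrix genes 10 were higher, with Thbs1 at 1.78, Ccn2 at 1.20 and Ccn1 at 1.19. Each of these named genes is also in the p53 or the immediate-early list. The immediate-early list had a median of 0.42, with 19 of 26 members higher and Egr1 at -0.47. Lcn2, an acute-phase iron-siderophore binder, was higher by 1.48.

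Among genes of liver metabolism, Fabp1, the liver fatty acid binding protein, differed by -1.19, and the fatty acid oxidation list had a median of -0.47, below all 10000 random lists. Pdk4, which restrains glucose oxidation, went the other way at 1.18. Hepatocyte identity genes had a median of -0.46 with 19 of 23 lower. NRF2 targets had a median of -0.29 with 20 of 21 lower, including the glutathione transferases Gsta3 (-1.02) and Gstm1 (-0.93) and the epoxide hydrolase Ephx1 (-0.69). All 6 expressed genes of xenobiotic metabolism were lower, with Cyp3a11 at -0.74. The lowest genes were Abat (-2.30), of GABA breakdown, Bbip1 (-2.06), the cyclin G family member Ccng2 (-1.76), Pxmp4 (-1.73) and the monocarboxylate carrier Slc16a7 (-1.73). Mitotic genes had a median of 0.01 and no member differed by 1.5-fold. Cholesterol synthesis genes had a median of -0.19, with 16 of 19 lower.

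APAP against AMAP at 2 h. At the same dose and time the regioisomers differed in stress, p53 and mitotic genes and in Krt7 and Krt19. Atf3 was 11.5-fold lower in APAP than in AMAP, and Ddit3 and Jun differed by -2.80 and -2.46 log2. Of 31 p53 targets 29 were lower in APAP, and 22 of 23 mitotic genes were higher. There were 35 genes at least 2-fold higher and 85 at least 2-fold lower in APAP.

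The p53 list had a median of -0.39, below all 10000 random lists, with Trp53inp1 at -2.06, Btg2 at -1.90, Gadd45a at -1.50, Mdm2 at -1.32 and Cdkn1a at -1.13. The ATF4 list had a median of -0.70 with 23 of 24 genes lower, among them Chac1, a glutathione-degrading enzyme, and Nupr1, both at -1.21. The immediate-early list had a median of -0.44, with Egr1 at -1.94; Fos differed by -2.11, but its value in APAP, 4.84, lies below the median of all values. Txnip, which binds thioredoxin, differed by -2.48. Mitotic genes had a median of 0.61, above all random lists, with Ube2c at 1.51 and the mitotic kinase Plk1 at 1.39. All 19 ribosome biogenesis genes were higher in APAP, with a median of 0.36. Lamb3 (2.28), Spib (1.52), Adam12 (1.48), Krt7 (1.08) and Krt19 (1.03) were also higher, and the 3 cholangiocyte markers had the largest median of any tested list, 1.03. NRF2 targets had a median of -0.24 with 19 of 21 lower. Among the lists with medians close to 0 were ER chaperones (-0.03), DNA replication (0.03), matrix (0.03), cholesterol synthesis (-0.045) and hepatocyte identity (-0.07).

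**Figure D3:**
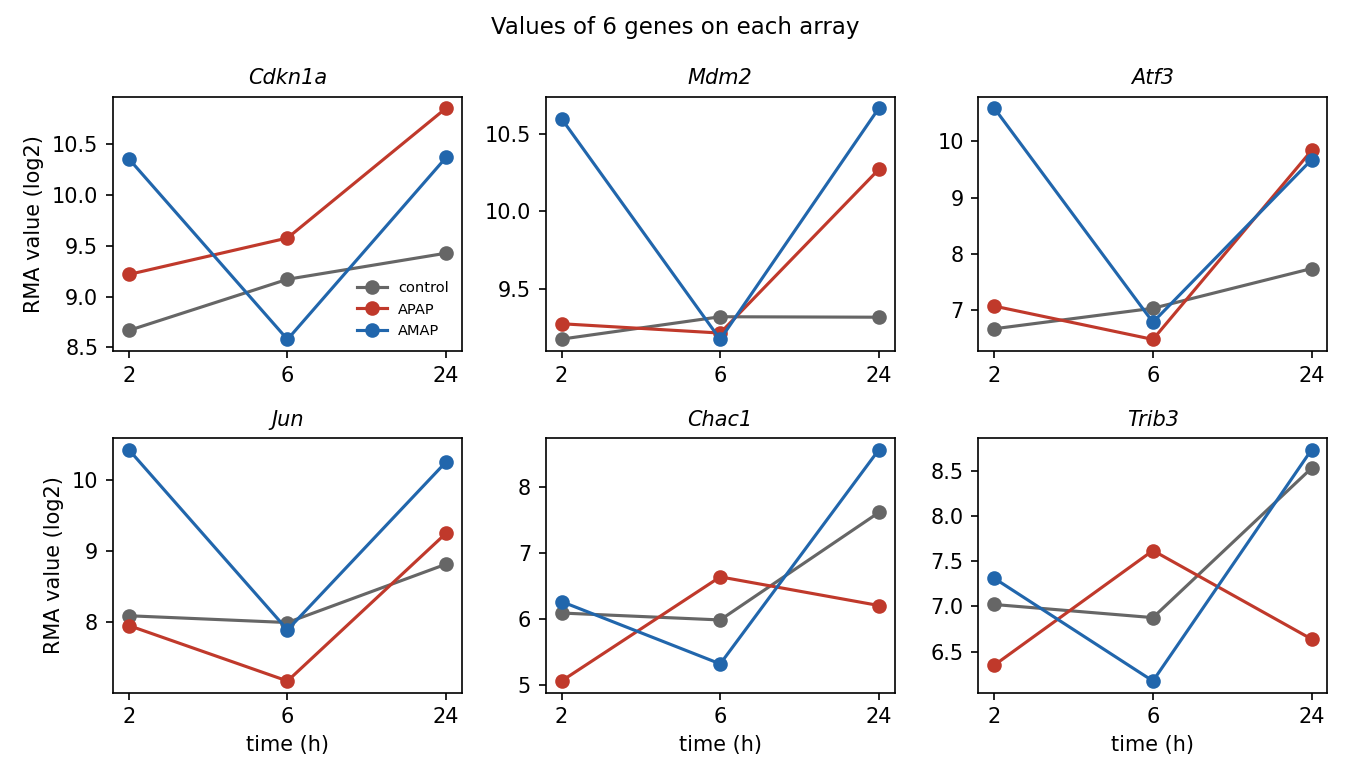
RMA values (log2, y axis) of Cdkn1a, Mdm2, Atf3, Jun, Chac1 and Trib3 on each of the 9 arrays, by time in h (x axis, not to scale), with lines joining the arrays of control, APAP and AMAP. APAP minus AMAP is -1.13 for Cdkn1a and -3.53 for Atf3 at 2 h, and -2.37 for Chac1 and -2.10 for Trib3 at 24 h.

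APAP against AMAP at 24 h. By 24 h the order of the compounds on p53 targets had turned: 23 of 31 were higher in APAP, with a median of 0.48 log2, above all 10000 random lists. Cdkn1a was higher in APAP by 0.48, while Mdm2 was lower, at -0.39. Genes of the ATF4 stress response were lower in APAP, 21 of 24, with Chac1 at -2.37, Nupr1 at -2.18 and Trib3, a pseudokinase, at -2.10. Cholesterol synthesis genes were lower, 17 of 19. There were 129 genes at least 2-fold higher and 104 at least 2-fold lower in APAP, or 106 and 109 under cyclic loess, and a further probe set followed in 45.8% of the genes that had one.

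The ATF4 list had a median of -0.64 and the cholesterol list one of -0.50, both below all 10000 random lists; Hmgcs1, the synthase of HMG-CoA, differed by -1.52 and Fdps by -1.02. Among p53 targets Btg2 was higher in APAP by 0.29, and Gadd45a and Trp53inp1 lay at -0.87 and -0.39. Among hepatocyte genes 16 of 23 were higher, including the fibrinogen chain Fgb (1.51), Ahsg (1.32) and Apoa1 (1.30). Mitotic genes had a median of 0.34 with 18 of 23 higher. In fatty acid metabolism, Pdk4 was higher by 1.12 and Angptl4, an inhibitor of lipoprotein lipase, by 1.01. The NF-kB list had a median of -0.30, with the chemokine Ccl7 at -1.11. Other genes at the ends of the range were Crim1 (2.25), Phip (2.14), Pm20d1 (2.14), the carboxylesterase Ces2g (2.00) and Banp (1.87), and Slc17a1 (-2.25) and Fmo1 (-2.15). For Nupr1 and Trib3 both probe sets were 2-fold apart; for Phip 1 of 4 was.

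Each compound against control at 24 h. Both treated arrays stood apart from the control by the spike-in ratio, and a further probe set followed in 51.0% of genes for APAP and 38.5% for AMAP. Within that limit, p53 targets were higher than control with either compound, by a median of 0.84 in APAP (25 of 31) and 0.30 in AMAP (23 of 31). All expressed genes had medians of 0.116 and 0.096. Cdkn1a was higher by 1.42 and 0.94, Btg2 by 1.67 and 1.38, and Mdm2 by 0.95 and 1.35. Atf3 was higher by 2.10 and 1.94. In AMAP the immediate-early genes Egr1 (2.19), Fos (2.02, from 4.93), Ier2 (1.84) and Zfp36 (1.65) led the higher genes.

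In APAP, 239 genes were at least 2-fold higher and 267 lower; in AMAP the counts were 51 and 183. At 1.5-fold the balance turned, to 1052 and 669 in APAP and 657 and 558 in AMAP, and under cyclic loess it moved the other way, to 105 and 349 in APAP and 15 and 255 in AMAP. The DNA polymerase Polk (1.86) and Gtse1 (1.76) were the p53 targets farthest above control in APAP. Txnip (2.52), the xylulose reductase Dcxr (2.39), the receptor Notch3 (2.34), Dcaf4 (2.25) and Pm20d1 (2.14) were highest in APAP, and both probe sets of Txnip and of Notch3 were 2-fold apart. ATF4 genes had a median of -0.41 in APAP, with Nupr1 at -2.43, Cth, of cysteine synthesis, at -1.92 and Trib3 at -1.89, against 0.13 in AMAP. Cholesterol genes had a median of -0.50 in APAP, with Sc5d at -1.47 and Hmgcs1 at -1.24, and of 0.18 in AMAP. The lowest genes of APAP were Qk (-3.50), Fscn1 (-3.04), Hmgn5 (-2.97), Hnrnph2 (-2.76) and Rnpc3 (-2.74). Those of AMAP were Ube2e1 (-2.87), Rnpc3 (-2.71), Hnrnph2 (-2.64), Rnf138 (-2.56) and Ell2 (-2.51). Of the 2 probe sets above the median of each gene, 1 was 2-fold lower in APAP for Qk and Fscn1, and the other of Fscn1 did not go the same way; for Rnpc3 both were 2-fold lower with either compound.

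The 6 h arrays. At 6 h the p53 list as a whole did not stand out from control: the 31 targets had a median of -0.07 in APAP and -0.15 in AMAP, inside the middle of the random lists at percentiles 42.0 and 19.7. Cdkn1a lay at 0.41 and -0.59 and Mdm2 at -0.10 and -0.15. Pmaip1 was higher in AMAP by 1.83, against 0.99 at 2 h and -1.07 at 24 h. The APAP array stood apart by the spike-in ratio; APAP against control gave 119 genes at least 2-fold higher and 362 lower, and APAP against AMAP gave 281 and 556. AMAP against control gave 73 and 17. A further probe set followed in 50.0%, 49.0% and 28.0%. Without the filter on low values APAP against AMAP turned to 801 higher and 601 lower, and at 1.5-fold AMAP against control turned to 309 higher and 334 lower.

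In APAP the immediate-early list had a median of -0.49, with the MAPK phosphatase Dusp6 at -2.21 and Egr1 at -1.79. The ATF4 list had a median of 0.15 in APAP and -0.46 in AMAP, so that it was higher in APAP than in AMAP by 0.45, with Trib3 at 1.44 and Chac1 at 1.32. The extremes of APAP against control were Ttll3 (1.99), Spib (1.97), the glucose carrier Slc2a2 (1.82), Lrrc18 (1.67) and Serpina10 (1.66), and Pnn (-2.78), Hivep1 (-2.71), Plod2 (-2.66), Commd6 (-2.59) and Zfp672 (-2.55). Those of AMAP against control were Fscn1 (2.58), Spib (2.06), the gap junction gene Gja1 (1.95), Hmgn5 (1.94) and Plscr2 (1.93), and Arid5a (-1.40), Ints6l (-1.18), Txnrd3 (-1.18), Stbd1 (-1.14) and Naaa (-1.10). Between the compounds they were Sv2a (2.18), Ttll3 (2.18), Gjb2 (2.14), Adarb1 (2.08) and Srrm4 (1.94), and Hmgn5 (-3.84), Phip (-3.51), Hivep1 (-3.25), Ube2e1 (-3.23) and Ktn1 (-3.18). For Phip 3 of 4 probe sets were 2-fold lower.

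**Figure D4:**
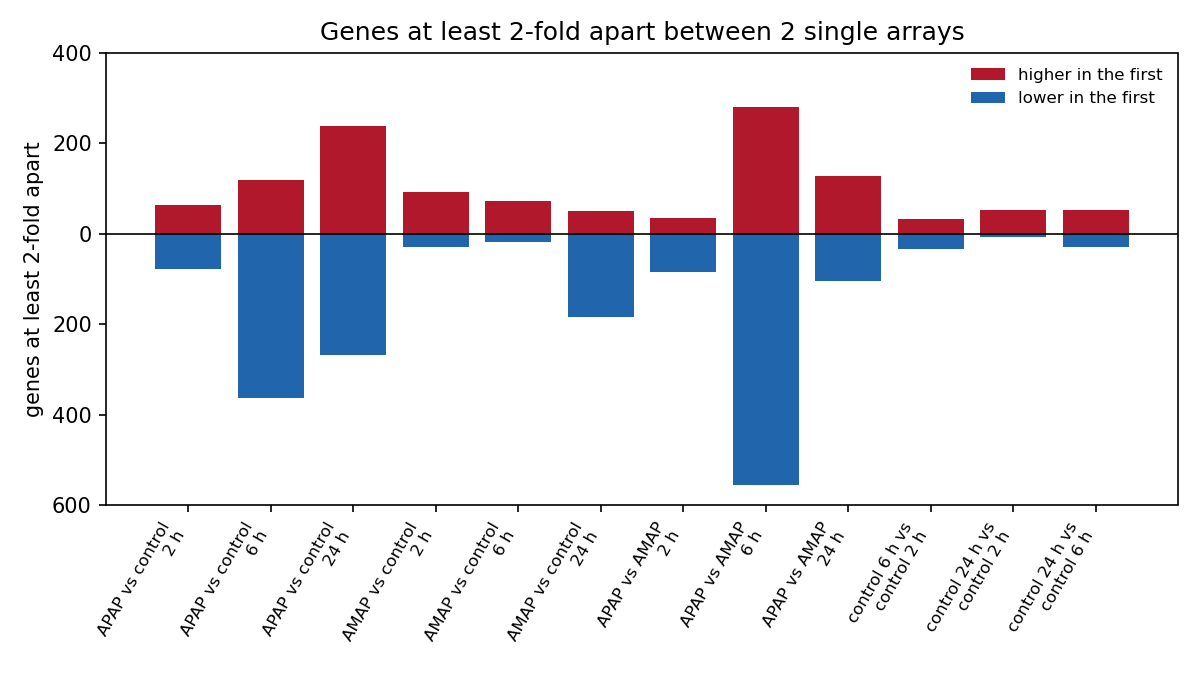
Bars give the number of genes at least 2-fold higher (up) and lower (down) in the first of 2 single arrays (y axis), for 9 comparisons of treatments and 3 between control arrays of different times. APAP against AMAP at 6 h has the most, 837, and the control arrays differ in 59 to 82.

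Effects shared by the 3 times. A fit with time as a block asked which genes differed between treatments in the same way at 2, 6 and 24 h. Averaged over the times, p53 targets and immediate-early genes had higher medians in AMAP than in control and mitotic genes a lower one, and cholesterol synthesis genes had a lower median in APAP. Each of these lists had an adjusted p = 0.463 with an estimated correlation. At 6 h alone the medians of p53 targets and immediate-early genes in AMAP lay below 0, at -0.147 and -0.115, and that of cholesterol genes in APAP above it, at 0.057. All expressed genes had a median of -0.104 in AMAP and -0.049 in APAP at that time. Among the random lists the 3 medians lay at percentiles 19.7, 40.7 and 89.3, so they show no clear reversal. At each of the 3 times Cxcl10 was higher in AMAP, and Krt7, Krt19 and Timp1, an inhibitor of metalloproteinases, were higher in APAP. No single gene passed limma's test at an adjusted p under 0.05 in any of the 3 contrasts, with 0 of 6700 genes each, and none did in any other setting. At an unadjusted p under 0.05 there were 514 genes for APAP against control and 30 for AMAP against control. For APAP against AMAP there were 285. Of these counts among 6700 genes, only the 514 exceeds the share of 0.05 that would lie there by chance. In other settings with the filter on low values the counts ranged over 347 to 570, 6 to 217 and 207 to 404. These ranges leave out the fit without the 3 arrays that stand apart, where APAP keeps only its 2 h array. Without the filter they were 902, 56 and 606, but of 12393 genes tested, so they are not directly comparable.

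In camera's test with a preset correlation, 18 of 60 tests of lists passed; none passed with an estimated correlation, and none in fry. Other groupings of the same arrays also gave up to 8 list calls, so these calls are weak evidence. Against control, AMAP-treated cells had p53 targets higher by a median of 0.29 (27 of 31, adjusted p = 8.34e-13), immediate-early genes by 0.34 (22 of 26, adjusted p = 2.67e-15) and mitotic genes at -0.29 (23 of 23 lower, adjusted p = 3.04e-13). NF-kB (0.04, 11 of 15, adjusted p = 0.00151), matrix (0.21, 9 of 11, adjusted p = 0.00232) and cholangiocyte genes (0.42, 3 of 3, adjusted p = 0.0218) were higher as well. For each of these 6 lists the adjusted p = 0.463 with an estimated correlation. Ribosome biogenesis was higher (0.07, 17 of 19, adjusted p = 0.0185), and hepatocyte (-0.11, 17 of 23, adjusted p = 0.0416) and cholesterol genes (-0.12, 15 of 19, adjusted p = 0.0438) were lower, each with an adjusted p = 0.692 with an estimated correlation. The hepatocyte list turned upward without the 2 h arrays (adjusted p = 0.922); its medians at the 3 times were -0.29, 0.045 and 0.00. The p53, immediate-early, mitotic and NF-kB calls held when any time was left out, and the other 5 ended without the 2 h arrays. Without the 24 h arrays these 5 ended as well, and without the 6 h arrays the cholesterol (adjusted p = 0.356), cholangiocyte (adjusted p = 0.122) and ribosome biogenesis calls (adjusted p = 0.0506). The cholesterol call also ended with the mean of probe sets (adjusted p = 0.264) and loess (adjusted p = 0.0734), the hepatocyte call with loess (adjusted p = 0.0784) and the spike-in ratio as a covariate (adjusted p = 0.0736), and that of ribosome biogenesis without the filter (adjusted p = 0.0581). Without the 3 arrays that stand apart the hepatocyte (adjusted p = 0.288), matrix (adjusted p = 0.0728) and ribosome biogenesis calls (adjusted p = 0.373) ended.

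APAP against control had matrix genes higher by 0.23 (9 of 11, adjusted p = 0.0218), the 3 cholangiocyte markers by 0.79 (adjusted p = 0.039) and cholesterol genes lower, median -0.39 (16 of 19, adjusted p = 0.00101), each with an adjusted p = 0.463 with an estimated correlation. The p53 targets were higher by 0.28 (22 of 31, adjusted p = 0.0307) and ribosome biogenesis by 0.20 (18 of 19, adjusted p = 0.0045), both with an adjusted p = 0.692 with an estimated correlation. Without the 2 h arrays all 4 lists called higher ended, p53 at an adjusted p = 0.0865, cholangiocyte at 0.331, matrix at 0.447 and ribosome biogenesis at 0.664, and without the 24 h arrays p53 had an adjusted p = 0.94 and cholesterol 0.163. The p53 call also ended without the filter on low values (adjusted p = 0.226), as did that of ribosome biogenesis (adjusted p = 0.0578). The cholangiocyte call ended under loess (adjusted p = 0.0557) and without the 6 h arrays (adjusted p = 0.055). Without the 3 arrays that stand apart APAP keeps only its 2 h array, where the p53 median against control was 0.10. APAP against AMAP had mitotic genes higher by 0.24 (19 of 23, adjusted p = 0.000422), and ATF4 (-0.21, 19 of 24, adjusted p = 0.000546) and immediate-early genes (-0.42, 20 of 26, adjusted p = 0.000546) lower, each with an adjusted p = 0.692 with an estimated correlation. Cholesterol genes were lower (-0.19, 15 of 19, adjusted p = 0.00996; adjusted p = 0.659 with an estimated correlation). Of these the mitotic and ATF4 calls ended without the 2 h arrays, and the ATF4 and cholesterol calls without the 24 h arrays. Without the 3 arrays that stand apart this contrast rests on the 2 h array of APAP. At 2 h the cholesterol median of APAP against AMAP was -0.045.

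Some members passed when adjusted over the list alone: Cxcl10 for AMAP (1.31, 95% interval 0.81 to 1.80), and for APAP Timp1 (0.99, 0.50 to 1.49), Krt19 (0.96, 0.23 to 1.69), Krt7 (0.79, 0.23 to 1.35), Ahr (-0.79, -1.32 to -0.26) and Cyp3a11 (-0.66, -1.16 to -0.16). No other list had a member that did. The adjustment was made within 1 list and 1 contrast at a time, with none across lists or contrasts. The lists concerned had only 3 to 15 expressed members, and none of these genes passed over all 6700 genes. The difference of APAP and AMAP over the 3 times was 0.12 for Cdkn1a, with a 95% interval of -0.81 to 1.04, and -0.56 for Mdm2, with -1.28 to 0.17, so the intervals leave open a 2-fold higher Cdkn1a and a 2-fold lower Mdm2 in APAP. The interval reached a median of 0.469 log2 to either side of the estimate over all genes, and for 5887 of 6700 genes it lay within 1 log2 of 0. For the p53 list APAP against AMAP had a median of 0.02 and a mean of -0.13. Of the markers of other cell types, 1 macrophage, 1 stellate or fibroblast, 0 endothelial and 3 of 6 measured cholangiocyte markers were expressed.

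**Figure D5:**
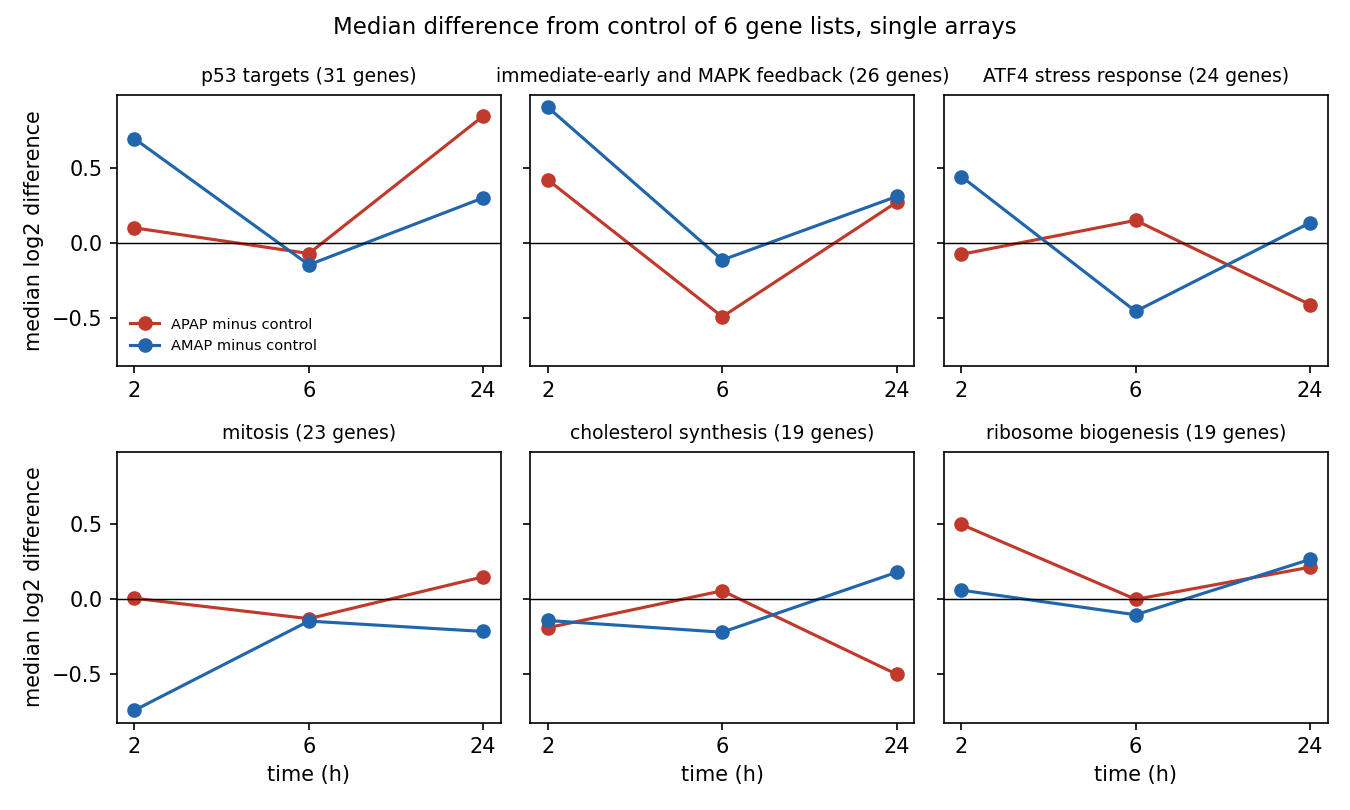
Median log2 difference from control (y axis) of 6 gene lists at 2, 6 and 24 h (x axis, not to scale), for APAP and AMAP, each point from 1 pair of arrays. For p53 targets AMAP lies above APAP at 2 h, 0.69 against 0.10, and below it at 24 h, 0.30 against 0.84.

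Change with time. A slope on log2 time was fitted to see which treatment differences grew or shrank. No gene passed in limma, 0 of 6700 in each contrast and 0 in every other setting, with 230, 66 and 134 genes at an unadjusted p under 0.05 for APAP against control, AMAP against control and APAP against AMAP. Each of these counts is below the share of 0.05 that would lie there by chance. The single-array medians gave the course of each list: p53 targets in AMAP went from 0.69 at 2 h to -0.15 at 6 h and 0.30 at 24 h, and in APAP from 0.10 to -0.07 and 0.84.

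Likeness of the responses. Across the 6700 expressed genes the APAP and AMAP responses, each against the same control array, correlated with Pearson's r = 0.518 at 2 h, -0.136 at 6 h and 0.644 at 24 h, and 0.495 for the effect shared by the times. Genes are not independent replicates, and unchanged groups simulated against a shared control gave r = 0.50. The covariance was 0.0608, -0.0245 and 0.157 at the 3 times, against 0.106 simulated, and 0.0261 against 0.0352 for the shared effect. The simulated spread includes effects at single times, which can make the simulated covariance and overlap too high. At 2 h 26 genes, among them Sprr1a and Csf2, were 2-fold higher in both and 9 lower in both, where independent lists would share 0.87 and 0.34. At 24 h 18 were higher and 93 lower in both, against 1.77 and 7.11, and at 6 h 4 and 3, against 1.28 and 0.91. Unchanged groups simulated against a shared control gave 43.8 higher and 43.6 lower in both. Of the observed overlaps only that of the 93 lower genes exceeds this, and at 24 h both treated arrays stood apart from the control. For lower genes at 2 and 6 h the simulated count could not be reached, since AMAP had only 30 and 17 genes lower. The comparison therefore cannot tell how much of the other overlaps comes from the shared control array.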

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

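The tests in this part were chosen only after the results were seen, apart from the splits of the arrays in the design; for the 3 arrays, the spike-in, actin and Gapdh tests, like the splits for the shared effect, were set after their values were known. A signal outside the measured genes was found in the bacterial dap control RNA. Its middle-to-3′ log2 ratio was -1.717 for APAP at 6 h, -1.583 for APAP at 24 h and -1.945 for AMAP at 24 h, while the other 6 arrays lay between -0.597 and -0.437.

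The lists below had a different effect at different times, by an unplanned camera test of the slope on log2 time; 19 passed at the preset correlation and none with an estimated correlation, where the lowest adjusted p = 0.763. With the spike-in ratio as a covariate 3 of the 19 ended: NF-kB (adjusted p = 0.0643) and ribosome biogenesis in APAP (adjusted p = 0.119), and p53 targets in AMAP (adjusted p = 0.0654). Another 3 were gained: ATF4 in APAP against AMAP, upward (adjusted p = 0.0261), mitosis in APAP (adjusted p = 0.00293), and glycolysis in AMAP (adjusted p = 0.00196); all had an adjusted p = 0.945 with an estimated correlation. The fit with the covariate leaves 1 residual degree of freedom, so the calls that ended or were gained are weak evidence. The values below are median log2 changes per doubling of time. Against control, APAP gave p53 targets 0.209, fatty acid oxidation 0.195, hepatocyte identity 0.149, ATF4 -0.139, NF-kB -0.133, cholesterol -0.109, ribosome biogenesis -0.04 and cholangiocyte -0.312. AMAP against control gave p53 targets -0.053, mitosis 0.084, ATF4 -0.073 and immediate-early -0.155. APAP against AMAP gave p53 targets 0.277, fatty acid oxidation 0.14, NRF2 targets 0.097, mitosis -0.076, ribosome biogenesis -0.107, cholesterol -0.151 and cholangiocyte -0.305. The covariate moved some of these far: ATF4 to -0.515 and mitosis to 0.272 in AMAP, ATF4 to -0.296 in APAP, and mitosis to -0.177 in APAP against AMAP.

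The 3 arrays that stand apart, APAP at 6 h and both compounds at 24 h, may differ in labelling or hybridisation: the dap ratio, read from RNA that is not the cells', left a gap of 0.986 log2 to the other 6. Degraded RNA stays open for the APAP arrays, where actin and Gapdh differ. The actin 3′ minus 5′ difference was 0.085 on APAP at 6 h and 0.126 on AMAP at 24 h, below the 0.265 to 0.47 of the other 6. On APAP at 24 h it was 0.277, inside that range. The Gapdh difference was -0.049 on APAP at 6 h and -0.096 on APAP at 24 h, above the -0.293 to -0.209 of the other 6. On AMAP at 24 h it was -0.246, inside that range, so neither gene points to degraded RNA on that array. A response of the cells as the whole cause would have moved further probe sets of the same genes along, as at 2 h in AMAP, where 97.1% followed; here 36.5% did. All 3 arrays are of treated cells, so a response of the cells may still be part of it, and these data cannot separate the parts.

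The p53 targets turned from lower to higher in APAP than in AMAP between 2 and 24 h. Further probe sets of 13 members gave medians of -0.459 and 0.46, so for these members the turn does not rest on single probe sets. The 26 of 31 members whose probe set has no suffix for shared probes gave -0.429 and 0.508. The turn thus does not rest on probe sets with that suffix. Whether those without it bind other transcripts was not tested. On the first principal component, which held 49.2% of the variance, the compared arrays lie close together (-0.288 and -0.243 at 2 h, 0.372 and 0.366 at 24 h). Its removal could therefore hardly move the medians, which were then -0.406 and 0.476, and is no separate test. With the spike-in ratio as a covariate the slope went from 0.277 to 0.282 (camera, adjusted p = 3.88e-09, and adjusted p = 0.945 with an estimated correlation). That fit leaves 1 residual degree of freedom, so it cannot show that the turn is free of the spike-in shift. The close loadings leave little of the turn to that axis. With 1 array per group, variation between cultures may account for the turn as well as a later p53 response to APAP, and these data cannot tell them apart.

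AMAP against control at 6 h, led by Fscn1, Hmgn5 and Gja1, lay along the axis of the 3 arrays in reverse: r = -0.619 across genes with the 24 h difference of treated and control arrays, which shares no array with it, against 0.072 for AMAP at 2 h. Of 62 expressed genes 2-fold higher at 6 h, 58 lay below 0 on that axis. AMAP at 6 h had the highest dap ratio of the 9 arrays, -0.437, and the lowest loading, -0.362. The control array of 6 h had a loading of -0.01, the nearest of the other arrays to the 3, though its dap ratio of -0.508 was not shifted. These differences between AMAP and control may thus come from the same array-to-array variation, on either array.

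Other splits of the 6 arrays of each contrast, with 3 on each side, are too few for a share under 0.05. For the shared effect all 10 splits had as many genes as the real 0 in each contrast; the highest other split had 0 for APAP against control, 3 for AMAP against control and 451 for APAP against AMAP. The split with 451 sets APAP at 6 h and both compounds at 24 h against the rest, which points to a structure of the samples other than treatment. For lists, 4 of 10 splits had as many calls as the real 5 for APAP against control (highest other 8), 1 of 10, the real split, as many as 9 for AMAP against control (highest other 7), and 6 of 10 as many as 4 for APAP against AMAP (highest other 7). For the slopes, all 4 splits had as many genes as the real 0 in each contrast, and the highest other was 0.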

How the results depend on the processing

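Treatments were compared within time, since time was a block in the shared fit. Replicates could not be paired, because each treatment and time has 1 array. No gene passed the shared fit or the slope fit in any setting. At 1.5-fold more genes differ by construction: 702, 1780 and 1721 for APAP against control at 2, 6 and 24 h, 451, 643 and 1215 for AMAP against control, and 552, 2524 and 1096 for APAP against AMAP. Without the filter, more dim genes counted at 6 h: 796 for APAP against control (395 higher, 401 lower) and 1402 for APAP against AMAP. Cyclic loess left each total within 1.5 times but moved the balance, to 105 higher and 349 lower for APAP at 24 h, 15 and 255 for AMAP at 24 h, 114 and 4 for AMAP at 6 h, and 144 and 685 for APAP against AMAP at 6 h; the cause was not tested. Of the 18 list calls, 17 held with the mean of probe sets, 15 without the filter and 15 under loess. With an estimated correlation or fry 0, 0 and 0 lists passed in the 3 contrasts. Against the preset 0.01, the estimated correlation was 0.388 for immediate-early genes, 0.398 for p53, 0.441 for mitosis, 0.514 for ribosome biogenesis and 0.524 for ATF4. It was 0.0098 for NF-kB, close to the preset. The adjusted p of that list in camera, AMAP against control, still went from 0.00151 to 0.463. For NF-kB a higher correlation therefore does not account for the lost call, and what else does was not tested. Leaving out a time gave 1 to 8 lists for APAP against control, 4 to 7 for AMAP against control (5 without 2 h, 4 without 24 h) and 2 to 5 for APAP against AMAP. Hepatocyte identity in AMAP turned upward without the 2 h arrays (adjusted p = 0.922), and had 0.00399 without 6 h. Of settings chosen after seeing the data, the spike-in covariate gave 8 lists for APAP against control. Leaving out the 3 arrays that stand apart leaves APAP only its 2 h array. Both contrasts with APAP then rest on that array and cannot show an effect shared by the times, so no list counts are given for them. For APAP against AMAP 7 lists passed without the filter. The cause was not tested. The correlation of the responses was -0.086 at 6 h, 0.579 at 24 h and 0.469 for the shared effect without the filter, and 0.668 at 24 h with the mean of probe sets; the cause was not tested. Of 783 named differences the mean of probe sets moved 136, and Ahr, APAP minus AMAP at 6 h, turned to 0.13; loess moved 10. Dim probe sets near background limit all small differences.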
